A study of Homo sapiens with 12 samples.

How the data were processed

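RNA of macrophages derived from THP-1, a human monocytic leukaemia cell line, was measured on Illumina expression beadchips, 1 array per sample. The 12 arrays fall into 6 groups of 2: untreated cells, cells given wild-type SAA1 and cells given a variant of SAA1 that differs at residue 72, each at 8 h and 24 h. Per the labels' protocols, RNA was amplified and labelled with biotin using a TotalPrep kit, and the cRNA was checked on a Bioanalyser. Dose, differentiation protocol and source of the proteins were not given in the sources used here.

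The values used were the authors' deposited intensities, linear probe signals made with GenomeStudio per the submitters' processing notes, whose version was not given in the sources used here. In the deposited table every array had a mean signal of 204.44, while the medians ran from 39.78 to 46.39, so the authors had scaled the arrays to a common mean. The values were not on a log scale, not quantile-normalized and not background-subtracted, as judged from the values. A second table of signals with detection p-values names its 12 signal and 12 detection columns by numbers that no label ties to a sample. Those 24 columns were not used here. The planned background correction with detection p-values, the filters on detection p and the chip as a block therefore could not be run. As set out for a table that is already normalized, the deposited intensities were taken to the log2 scale and tested as they were.

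Of 48803 probes, 28098 had 1 gene symbol in the platform annotation, 13 had several and 20692 had none there. Matching by gene ID to a current RefSeq gene table found 28059 of them and changed 0 symbols. Probes without exactly 1 symbol were tested but are not named. The brightest 60% of probes by mean log2 intensity were kept (29282), and each gene was represented by its probe of highest mean, which left 24238 probes, here called genes, of which 14183 had a symbol. For 3827 genes more than 1 probe was kept, and disagreement between probes is stated for passing genes named by the rule below.

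A background limit was estimated for each array as the 99th percentile of a normal distribution fitted to the lower side of its low-signal mode. The limits lay between signals of 50.25 and 58.67, and 28.00% to 30.22% of probes lay above them. Where a gene was not above background on either array of a group, its fold is given as a lower bound ("at least"), computed against the higher of that limit and the measured value. For arrays the number of arrays, 2 per group, limits the precision, and the median standard error of a difference was 0.163 log2. Arrays of 1 group correlated across genes with Pearson's r of 0.9877 to 0.9924, and the SD of their log2 difference was 0.219 to 0.266. None of the pairs held identical values. The labels do not say that the 2 arrays of a group come from separate cultures, so p-values measure only the spread between these samples, which may be technical.

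All arrays entered 1 linear model with 6 group means (limma 3.58.1 in R 4.3.3, lmFit and eBayes), which leaves 6 residual degrees of freedom, with 23.18 prior degrees of freedom. The comparisons were wild-type SAA1 against untreated and variant against wild-type SAA1 at each time, as in the study design. Variant against untreated, untreated 24 h against 8 h, and the differences of these effects between the times came from the same fit. P-values were two-sided and adjusted by Benjamini-Hochberg over the 24238 genes, and an adjusted p under 0.05 counted as passing. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

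The comparisons, their tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Named for each design comparison were the 10 largest increases and the 10 largest decreases among passing genes whose arrays did not overlap, and up to 4 passing members of each list. Where fewer than 10 passed, the 5 genes of lowest p were named as well. SAA1, SAA2, IL1B, TNF, IL6, CXCL8, IL10, IL12B, IL23A, CSF3, TLR2, FPR2 and ABCA1 were always named. For the other comparisons the 5 highest and 5 lowest were named. The 26 lists were NF-kB targets, pro-inflammatory cytokines, chemokines, interferon-stimulated genes, anti-inflammatory and feedback regulators, markers of alternative (M2) activation, matrix metalloproteinases and remodelling, cholesterol efflux and lipid handling, cholesterol biosynthesis, SAA receptors and Toll-like receptor signalling, inflammasome, acute phase and complement, metallothioneins and zinc transport, NRF2 targets, hypoxia and glycolysis, cell cycle, unfolded protein response, heat shock, MHC and co-stimulation, immediate early genes, myeloid identity, apoptosis regulators, 3 lists of other cell types (lymphocyte, epithelial and fibroblast, hepatocyte and erythroid) and reference genes. Lists were tested with camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the 26 lists. Counts adjusted over the list alone are given beside those over all genes.

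Calls were tested on simulated data. In simulated arrays for wild-type SAA1 against untreated at 8 h with 50 genes changed at each size among 24238, the fit recovered 26.0% of 1.5-fold, 90.0% of 2-fold and 100.0% of 4-fold and 8-fold changes, with 9 false among 167 calls. Simulated unchanged groups for variant against wild-type SAA1 at 24 h gave 0 calls and 1171 genes with unadjusted p under 0.05. A simulated list of 20 genes shifted by 0.3 log2 was found (adjusted p = 8.31e-10, and 0.0091 with an estimated correlation), and 0 unshifted lists were called. These values come from a second random seed, set after the results of a first had been seen. Over 20 seeds, the second among them, 14.0% to 34.0% of 1.5-fold, 68.0% to 94.0% of 2-fold and 98.0% to 100.0% of 4-fold changes were recovered, with 2 to 11 false calls (1.2% to 6.7%) and 0 to 2 calls between the unchanged groups. The adjusted p of the shifted list ran up to 2.05e-06, and up to 0.0576 with an estimated correlation, and 0 to 1 unshifted lists were called. Genes were simulated as independent of each other, without array-wide differences, so these runs do not test list calls among correlated genes.

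The number of genes passing was recomputed with normexp background correction at an offset of 50 followed by quantile normalization, and with quantile normalization alone. Further settings were no filter, other handling of several probes, other variance settings, array weights and stricter thresholds. Fits to the compared groups or to 1 time point alone, the replicate number as a block and each array left out in turn were also run. Named genes and lists were recomputed so for the design comparisons alone. For variant against untreated and for time in untreated cells, lists were recomputed under other scalings only. Lists for the changes between times were not recomputed. Scaling to a common median, cyclic loess, 2 filters on the estimated background and the selection of genes called for the mean of both proteins were added after the data had been seen.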

Results

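The series measured gene expression in THP-1-derived macrophages left untreated or given serum amyloid A1 (SAA1), an acute-phase protein carried by lipoproteins. Cells were given wild-type SAA1 or a variant altered at residue 72, for 8 h or 24 h, with 2 arrays in each of the 6 groups. Between 13667 and 14749 of the 48803 probes on an array lay above its estimated background. Values are log2 intensities, differences are log2 changes with their standard error, and every adjusted p comes from limma with n = 2 per group.

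The comparison of wild-type SAA1 with untreated cells at 8 h asks what SAA1 does to these macrophages early on. Chemokine genes were among those that rose most. CCL4L1, a copy of the gene for the chemokine MIP-1 beta, went from 7.58 ± 0.03 to 11.83 ± 0.11 (SD, n = 2), a 19.1-fold change (4.25 ± 0.16, adjusted p = 2.01e-17). CCL1, a ligand of CCR8, rose by 3.85 ± 0.20, and CCL3, which encodes MIP-1 alpha, by 3.19 ± 0.17 (adjusted p = 1.46e-14 and 2.01e-14). CXCL8, the neutrophil chemoattractant interleukin 8, rose by 2.11 ± 0.16 from an already high level of 12.26 ± 0.06. CCL3L1 and CCL3L3 rose by 2.82 and 2.33, but they are near-identical paralogs of CCL3, as CCL4L1 is of CCL4. Within each of these families, which copy was measured is uncertain. A second, dim CCL4L1 probe changed by 0.25 and did not pass.

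Of the 22 chemokines tested, 10 rose and 0 fell at 8 h (14 rose adjusted over the list alone), with a median change of 0.59. CXCL10, a chemokine gene counted in the interferon-stimulated list instead, rose at least 2.25-fold. Of 18 pro-inflammatory cytokines, 5 rose (7 over the list alone). IL23A, the subunit that makes interleukin 23, was not above background in untreated cells and rose at least 6.54-fold. EBI3, a subunit of interleukins 27 and 35, rose by 2.18 ± 0.16, IL1B by 1.36 ± 0.16 (adjusted p = 2.44e-06), and TNF by 1.24 ± 0.16 (adjusted p = 5.61e-06). Of 24 NF-kB targets, 9 rose (19 over the list alone), with a median of 0.52. They included SOD2, the mitochondrial superoxide dismutase (2.37 ± 0.17, with a second probe at 2.89 and a dim one at 0.74 that did not pass), IER3 (1.23) and PTGS2, the inducible cyclooxygenase (1.22 ± 0.21), whose second, dim probe changed by 0.35 and did not pass. Camera gave adjusted p-values of 1.87e-46, 3.43e-20 and 7.31e-36 for chemokines, cytokines and NF-kB targets, and 5.70e-04 for each with an estimated correlation.

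Further lists rose with smaller counts. Of 20 feedback regulators 2 rose (6 over the list alone): TNFAIP6, a hyaluronan-binding protein induced in inflammation, rose by 3.94 ± 0.19 and ZC3H12A, an RNase that degrades cytokine mRNA, by 0.99 ± 0.16 (adjusted p = 2.70e-04). A second, dim TNFAIP6 probe changed by -0.15. Of 20 remodelling genes 3 rose (5 over the list alone), namely SERPINE2 (0.82), TIMP3 (0.65) and PLAUR (0.65), whose other PLAUR probes changed by 0.40 and -0.04 without passing. Of 18 MHC and co-stimulation genes 1 rose (4 over the list alone), the co-stimulatory receptor CD40 (2.11 ± 0.16, adjusted p = 1.47e-10). Of 15 NRF2 targets 0 passed over all genes and 3 rose over the list alone, with a median of 0.22, and of 29 interferon-stimulated genes 1 rose over all genes and over the list alone, CXCL10. With an estimated correlation the adjusted p was 0.0138 for feedback regulators, 0.0070 for remodelling, 0.0027 for MHC, 0.0095 for NRF2 targets and 0.0438 for interferon-stimulated genes. The interferon list reached 0.0821 to 0.224 with the estimated correlation under the 4 other scalings tried. With a common median the feedback, remodelling and NRF2 lists gave 0.0711, 0.129 and 0.0515. LAMP3, a marker of dendritic cell maturation, rose at least 5.82-fold, SLC2A6, a glucose transporter family member, by 2.38 ± 0.15, and TNFAIP2 by 1.70 ± 0.15.

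Preset camera calls that ended with an estimated correlation were cholesterol biosynthesis (0 of 17 passed, 1 over the list alone, adjusted p = 0.0636 with an estimated correlation), hypoxia and glycolysis (1 rose and 1 fell of 22, adjusted p = 0.110) and immediate early genes (1 of 21 rose, 3 over the list alone, adjusted p = 0.186). In the hypoxia list the glucose transporter SLC2A1 rose by 0.79 and the angiogenic factor VEGFA changed by -0.73. The immediate early member was FOSB (1.25 ± 0.28), whose wild-type arrays differed with an SD of 0.91. Without wild-type replicate 1 its change was 0.61 (adjusted p = 0.516). The remaining lists were not called: OLR1, a receptor for oxidized LDL, rose by 1.60 ± 0.16 among 23 lipid-handling genes, P2RX7 rose (0.74) and CD14, the LPS co-receptor, fell (-0.66) among 20 SAA receptor and Toll-like receptor genes, MT2A rose (0.71) among 10 metallothionein and zinc genes, and BID rose (0.77, with a second probe at 0.53 not passing) among 18 apoptosis regulators. None passed among 17 markers of alternative activation, 15 inflammasome, 17 acute phase, 30 cell cycle, 19 unfolded protein response, 14 heat shock, 26 myeloid identity, 10 lymphocyte, 5 epithelial and fibroblast, 7 hepatocyte and erythroid and 13 reference genes. Over the list alone 1 to 3 members moved in the alternative activation, lipid-handling, SAA receptor, metallothionein, cell cycle, unfolded protein response, myeloid and apoptosis lists. Median and mean differed in sign for lipid handling (-0.06 and 0.03), myeloid identity (-0.01 and 0.02), the inflammasome and the epithelial list, and apoptosis regulators had a negative median and a test pointing up. The reference genes had a median change of 0.09.

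The largest decreases at 8 h were in CHRM3, a muscarinic acetylcholine receptor (-1.35 ± 0.16, adjusted p = 1.40e-06), LOXL4, a lysyl oxidase family member (-1.23 ± 0.17, adjusted p = 2.09e-05), VCL, which encodes the focal adhesion protein vinculin (-1.03 ± 0.15, adjusted p = 8.95e-05), and GJA1, the gap junction protein connexin 43 (-1.03 ± 0.16). RGS4 (-0.96), XYLT1 (-0.96), ADCY1 (-0.90), RAP2A (-0.89), CYSLTR1 (-0.88) and RAB11FIP5 (-0.85) followed. Both VCL probes fell. Second probes of ADCY1 (-0.31), CD14 (-0.28) and VEGFA (-0.03) did not pass. Of the always-named genes, ABCA1, the cholesterol efflux pump, changed by 0.36 ± 0.17 (adjusted p = 0.435), TLR2 by 0.16 and IL10 by 0.13, none passing. SAA1, IL6 and CSF3 were not above background in either group. SAA2, IL12B and FPR2 were not above background on any array and were not tested.

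At 8 h, 171 of 24238 genes passed, 131 higher and 40 lower, against 2617 with unadjusted p under 0.05 where chance gives 1212. The split was 170 higher and 112 lower with normexp and quantile normalization, and 215 higher and 14 lower with arrays shifted to a common median, which moved the median of all genes by 0.110. Calls numbered 92 without untreated replicate 1, 84 without untreated replicate 2 and 108 without wild-type replicate 1, and 26 of the 41 named calls held in every setting. Without wild-type replicate 1 those of ADCY1, BID, CD14, FOSB, MT2A, P2RX7, PLAUR, PTGS2, RAB11FIP5, SERPINE2, SLC2A1, TIMP3 and VEGFA ended (adjusted p = 0.0515 to 0.516). Without untreated replicate 2 those of CYSLTR1, XYLT1, SERPINE2 and SLC2A1 ended (adjusted p = 0.0873 to 0.184). Those of ADCY1, BID, CD14, FOSB, MT2A, P2RX7, PLAUR, TIMP3 and VEGFA also ended without either untreated array (adjusted p = 0.0524 to 0.392), and that of RAB11FIP5 without untreated replicate 1 (0.163). Those of BID, CYSLTR1, MT2A, PLAUR, TIMP3 and VEGFA ended without wild-type replicate 2 (0.0511 to 0.167).

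**Figure D1:**
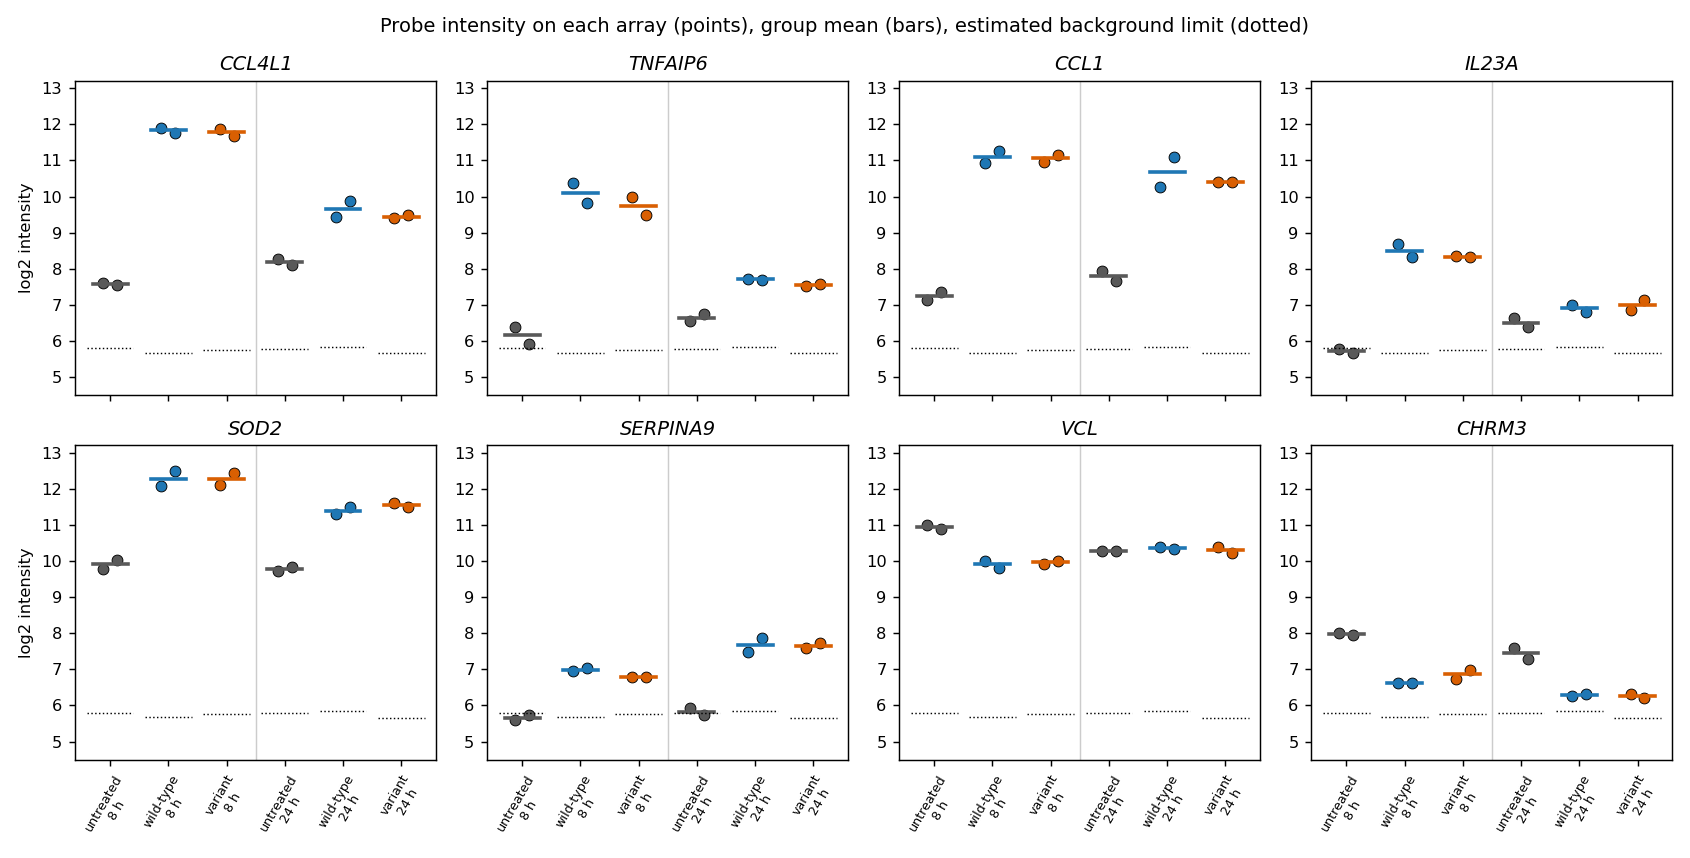
Log2 intensity (vertical axis) of 8 named genes on each of the 12 arrays (points) by treatment and time, with group means (bars) and the mean estimated background limit of each group (dotted). CCL4L1 rose by 4.25 with wild-type SAA1 at 8 h and by 1.46 at 24 h, while CHRM3 changed by -1.35 and -1.16.

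The same comparison at 24 h asks which of these responses remain a day after treatment. CCL1 led, from 7.80 ± 0.21 to 10.68 ± 0.60 (SD, n = 2), a 7.35-fold change (2.88 ± 0.20, adjusted p = 1.32e-10). SERPINA9, a serine protease inhibitor known from germinal centre B cells, rose by 1.86 ± 0.16 (adjusted p = 2.26e-08), EBI3 by 1.81 ± 0.16 and SOD2 by 1.62 ± 0.17 (adjusted p = 3.67e-08 and 1.07e-06), and both SERPINA9 probes rose. CCL4L1 (1.46), CCL3L1 (1.24) and CCL3L3 (1.07) rose, again with paralogs that may share signal. PARM1 (1.31), P3H2, a collagen prolyl hydroxylase (1.30), LAMP3 (at least 1.54-fold, its second probe at 0.23 not passing) and TNFAIP6 (1.05 ± 0.19, adjusted p = 0.0062) also rose. The dim probes of CCL4L1, TNFAIP6 and SOD2 did not pass at 24 h.

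Of 22 chemokines 5 rose at 24 h (14 over the list alone, median 0.50), CXCL8 among them at 0.78 ± 0.16 (adjusted p = 0.0278), with its other probe also passing. Of 18 cytokines 3 rose (5 over the list alone): EBI3, IL1A (0.97) and TNF (0.96 ± 0.16, adjusted p = 0.0013). Of 24 NF-kB targets 3 rose (8 over the list alone, median 0.24), SOD2, the NF-kB inhibitor NFKBIA (0.87) and IER3 (0.84). Adjusted p-values with an estimated correlation were 0.0071, 0.0071 and 0.0176, and 0.0514, 0.0603 and 0.163 with arrays shifted to a common median. Of 23 lipid-handling genes 0 passed and 2 fell over the list alone, with a median of -0.11 (adjusted p = 0.0483 with an estimated correlation). That p was 0.0957 to 0.341 under the 4 other scalings. Calls for interferon-stimulated genes (0 of 29 passed, 1 rose over the list alone) and remodelling genes (MMP19 rose by 0.80 among 20, 4 rose and 1 fell over the list alone) ended with an estimated correlation (adjusted p = 0.289 and 0.136). TNFAIP6 among 20 feedback regulators and MT2A (0.85) among 10 metallothionein and zinc genes passed in lists that were not called, and 0 members passed in the other 18 lists. Over the list alone 1 to 4 members moved in the alternative activation, SAA receptor, inflammasome, myeloid and apoptosis lists. Median and mean differed in sign for the unfolded protein response (-0.02 and 0.03), immediate early, myeloid, cell cycle, SAA receptor and hepatocyte lists, and the alternative activation list had a positive median and a test pointing down, none of them called. The reference genes had a median of -0.01.

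Lower at 24 h were FCGBP, which encodes a mucin-like IgG-binding protein (-1.26 ± 0.18, adjusted p = 2.67e-04), CHRM3 (-1.16 ± 0.16, adjusted p = 1.01e-04), PYROXD2 (-1.05), LOXL4 (-1.04), the inhibitory receptor CD300A (-0.94), the myosin MYO1G (-0.89), the transcriptional repressor HEY2 (-0.73) and ANTXR1, an anthrax toxin receptor (-0.70). A second, dim FCGBP probe and 3 further ANTXR1 probes did not pass. IL1B (0.43 ± 0.16, adjusted p = 0.465), IL23A (0.40), TLR2 (0.44), IL10 (0.14) and ABCA1 (0.03) did not pass. SAA1 was above background on 1 wild-type array and did not pass (adjusted p = 0.433), and IL6 and CSF3 were not above background in either group.

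At 24 h, 36 genes passed, 26 higher and 10 lower, against 1878 with unadjusted p under 0.05, and the split was 18 and 15 with a common median. Calls numbered 18 without wild-type replicate 1, 79 without wild-type replicate 2, 23 without untreated replicate 1 and 18 without untreated replicate 2. Of 27 named calls 11 held in every setting, those of CCL1, SERPINA9, EBI3, SOD2, CCL4L1, CCL3L1, CCL3L3, PARM1, P3H2, IL1A and CHRM3. BBX passed (1.10 ± 0.23), but its wild-type arrays had an SD of 0.87, and without wild-type replicate 1 its change was 0.48 (adjusted p = 0.527). Without that array the calls of ANTXR1, CD300A, CXCL8, HEY2, IER3, LOXL4, MMP19, MT2A, MYO1G, NFKBIA, PYROXD2, TNF and TNFAIP6 ended too (adjusted p = 0.0543 to 0.390). That of LAMP3 ended without untreated replicate 2 (adjusted p = 0.0886), and that of FCGBP with the mean over its probes (-0.69, adjusted p = 0.168). Those of ANTXR1, BBX, CXCL8, HEY2, MMP19, NFKBIA and TNFAIP6 also ended without either untreated array, those of CD300A, LOXL4, PYROXD2 and TNF without untreated replicate 1, and those of IER3, MT2A and MYO1G without untreated replicate 2 (adjusted p = 0.0543 to 0.633). Without wild-type replicate 2 those of ANTXR1, IER3 and MMP19 ended (adjusted p = 0.0534 to 0.117).

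Calls at the 2 times, which share no array, had 20 higher genes in common (0.141 expected for independent lists) and 5 lower genes, CD300A, CHRM3, FCGBP, HEY2 and LOXL4 (0.017 expected). The change of the response from 8 h to 24 h passed for 27 genes, 25 lower and 2 higher. The largest decreases in response were in TNFAIP6 (-2.89), CCL4L1 (-2.79), CCL3 (-2.53), MCOLN2 (-2.13) and IL23A, whose untreated 8 h level was not above background, so that only its wild-type level is compared (-1.60 from 8 h to 24 h). The response of VCL rose by 1.11. Over the list alone 7 of 24 NF-kB targets and 7 of 22 chemokines moved down in response (adjusted p = 0.0178 for both with an estimated correlation). The responses of cytokine, MHC, lipid-handling and NRF2 lists also moved down (adjusted p = 0.0310, 0.0178, 0.0322 and 0.0338 with an estimated correlation). These list tests were not recomputed under the other settings.

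The comparison of variant with wild-type SAA1 asks whether the change at residue 72 alters the response. At 8 h, 0 of 24238 genes passed in limma, with 1229 at an unadjusted p under 0.05 where chance gives 1212. The main cytokines stood at like levels. IL1B was 14.12 ± 0.12 with the variant and 14.16 ± 0.18 with the wild type, a difference of -0.04 (95% confidence interval -0.37 to 0.29). TNF differed by -0.09 (-0.40 to 0.23), CXCL8 by -0.10 (-0.43 to 0.23) and IL23A by -0.18 (-0.51 to 0.16). ABCA1 (-0.18), TLR2 (-0.005) and IL10 (-0.04) did not pass, and IL6, SAA1 and CSF3 were not above background. The genes of lowest p were CRIPTO3 (at least 1.17-fold higher, not above background with the wild type, adjusted p = 0.871), ECHDC1 (-0.64, with a second, dim probe at -0.15), and LSM11, NHLH1 and DPP4, which were not above background in either group.

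No list member passed at 8 h, over all genes or over the list alone. Preset camera put NF-kB targets, cytokines, chemokines, interferon-stimulated genes, cholesterol biosynthesis, cell cycle and MHC genes lower with the variant (adjusted p = 0.0104 to 0.0472), with medians of -0.05 to -0.13. With an estimated correlation these gave adjusted p = 0.314 to 0.334. The other 19 lists were not called, and in 7 of them median and mean, or median and test, differed in sign. The reference genes had a median of -0.04.

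At 24 h again 0 genes passed in limma, while 3058 had an unadjusted p under 0.05. TERF2IP, which encodes the telomere protein RAP1, was higher with the variant by 0.85 ± 0.16 (adjusted p = 0.117), RASSF4 by 0.78 (0.16 on a second, dim probe) and OSGEP, a tRNA modification enzyme, by 0.78, MRPL28, a mitochondrial ribosomal protein, by 0.75 (adjusted p = 0.128), and the zinc finger gene ZNF749, not above background with the variant, was at least 1.16-fold lower (adjusted p = 0.118), none of them passing. These 5 passed with trend and robust variance settings and with a common median. TNF differed by -0.35 (95% confidence interval -0.66 to -0.03, adjusted p = 0.363), CXCL8 by -0.15, IL1B by -0.11 and IL10 by -0.25. IL23A (0.09), ABCA1 (0.01), TLR2 (-0.23) and SAA1 (at least 1.05-fold lower, near background) did not pass, and CSF3 and IL6 were not above background.

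Over the list alone 6 of 22 chemokines fell with the variant at 24 h, with a median of -0.26 (-0.09 with a common median). The preset adjusted p was 0.0073 and the adjusted p with an estimated correlation 0.257. Unfolded protein response, heat shock and MHC lists were called higher (preset adjusted p = 0.0093, 0.0317 and 0.0317, and 0.207 for each with an estimated correlation), with medians of 0.16, 0.12 and 0.09. These calls ended under quantile normalization, normexp with quantile, and cyclic loess. NF-kB targets had a median of -0.09 while camera placed them up relative to other genes (adjusted p = 0.965), and the hypoxia (-0.06), remodelling (-0.06), cholesterol biosynthesis, acute phase and lymphocyte lists likewise, none of them called. With a common median the median of NF-kB targets was 0.09. Over the list alone 1 or 2 members moved in the cytokine, feedback, lipid-handling, metallothionein, immediate early, apoptosis and lymphocyte lists, and 0 in the other 18 lists. The reference genes had a median of 0.14. A common median moved the median of all genes by 0.173 and gave 282 calls, 281 of them higher. Every array's median signal (39.78 to 46.39) lay below its background limit (50.25 to 58.67). This scaling thus lines arrays up on probes at background and moves all genes of an array alike. Its calls in 1 direction cannot be told from that shift. Trend and robust settings gave 13 calls, testing every probe 2, and leaving out wild-type replicate 2 gave 8. The difference between the proteins changed from 8 h to 24 h for 1 gene, ZNF749 (adjusted p = 0.0222), which at 8 h was not above background with either protein, so that no size is given, against 2760 at an unadjusted p under 0.05, and for 0 genes with quantile normalization.

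To set the proteins side by side without favouring either, genes called for the mean of both against untreated were taken, a selection added after the data had been seen. At 8 h, 164 genes were higher, with a median response of 0.80 for the wild type and 0.68 for the variant. The variant lay below the wild type in 120 of them, with a median difference of -0.107 (range -0.61 to 0.37, camera p = 0.0068 with an estimated correlation). None of the 164 differed after adjustment and 16 did at an unadjusted p under 0.05. All 164 confidence intervals lay within 2-fold, but that limit is wider than the median response to either protein. With genes picked anew, the difference was -0.044 without variant replicate 2. Leaving out 1 array of a protein makes the picking favour genes high on its other array. That value therefore cannot show how firm the difference is. Of the 81 genes lower at 8 h, with a median response of -0.60 for the wild type and -0.65 for the variant, the variant lay below the wild type in 45, with a median difference of -0.039 (camera p = 0.182 with an estimated correlation). At 24 h, 32 genes were higher, with a median difference of -0.074 (camera p = 0.986 with an estimated correlation), and 12 were lower, with 0.087 (p = 0.138). For the genes higher at 24 h, picked anew under each scaling, this depended on the scaling. The difference passed at -0.127 with normexp and quantile, -0.137 with quantile and -0.143 with cyclic loess. It was 0.099 with a common median, not passing.

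The variant was also compared with untreated cells. At 8 h CCL4L1 rose by 4.21 ± 0.16, CCL1 by 3.82, TNFAIP6 by 3.59, CCL3 by 2.87 and CCL3L1 by 2.71, and CHRM3 (-1.12), LOXL4 (-1.03), VCL (-0.98) and RGS4 (-0.93) fell, with GJA1 at least 2.4-fold lower. At 24 h CCL1 rose by 2.60 ± 0.20, SERPINA9 by 1.83, EBI3 by 1.81, SOD2 by 1.76 and P3H2 by 1.29, and CHRM3 (-1.18), FCGBP (-1.06), LOXL4 (-1.01), PYROXD2 (-0.88) and HEY2 (-0.76) fell. Of 22 chemokines 9 rose at 8 h and 4 at 24 h, and of 24 NF-kB targets 5 and 1 (12, 6, 19 and 3 over the list alone). The estimated correlation gave adjusted p = 0.0011 for both lists at 8 h and 0.0404 and 0.0313 at 24 h, and the latter were 0.0600 to 0.161 under the 4 other scalings. Of 18 cytokines 5 rose at 8 h and 2 at 24 h (0.0171 at 24 h, and 0.101 with a common median). Feedback, remodelling, NRF2 and MHC lists were also higher at 8 h (adjusted p = 0.0123 to 0.0275 with an estimated correlation), but not with a common median (0.0723 to 0.153). Metallothionein and unfolded protein response lists were higher at 24 h (0.0404 and 0.0422), but under none of the 4 other scalings (0.0600 to 0.283).

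The variant changed 120 genes at 8 h, 82 higher and 38 lower, and 27 at 24 h, 21 higher and 6 lower. The splits were 103 and 24, and 107 and 5, with a common median, which moved the median of all genes by 0.116 at 24 h, and at 24 h 21 and 18 with normexp and quantile, 17 and 12 with quantile alone and 17 and 13 with cyclic loess. Calls at 8 h numbered 58 and 56 without untreated replicates 1 and 2 and 59 without variant replicate 1. At 24 h they numbered 10 and 14 without variant replicates 1 and 2 and 13 without either untreated array. Shared with the wild-type calls were 71 higher and 19 lower genes at 8 h (0.443 and 0.063 expected for independent lists) and 15 and 6 at 24 h (0.023 and 0.002). Across genes, the changes of the 2 proteins correlated with r = 0.695 at 8 h and 0.432 at 24 h, against 0.50 at either time in simulations of unchanged groups on the same controls. The covariance exceeded the simulated value by 0.0200 and 0.0036. The simulated 0.50 follows from the shared controls with independent noise per gene. These simulations held no array-wide differences, which can also move r, so the value of 0.432 cannot be read against it alone. With 2 untreated arrays per time, part of the shared calls may come from the shared controls.

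**Figure D2:**
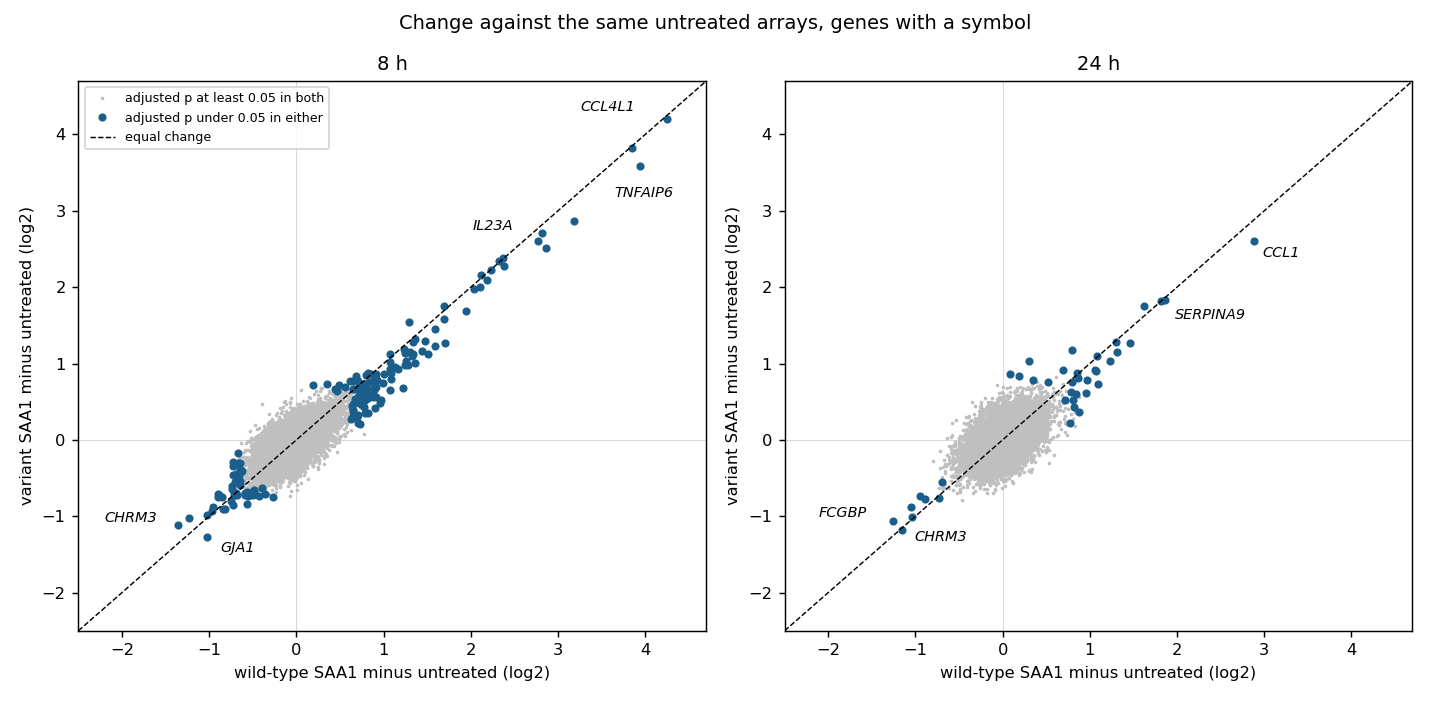
Log2 change with wild-type SAA1 (horizontal axis) and with variant SAA1 (vertical axis) against the same untreated arrays at 8 h and 24 h, with 1 point per gene with a symbol, filled blue where either passed, and a dashed line of equal change. CCL4L1 lay at 4.25 and 4.21 at 8 h and CCL1 at 2.88 and 2.60 at 24 h. In simulations over all tested genes, without array-wide differences, the shared untreated arrays alone gave r near 0.50.

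Untreated cells at 24 h were compared with those at 8 h to follow the course without SAA1. STC2, a stanniocalcin, rose by 2.52 ± 0.16 (adjusted p = 1.26e-11), DDIT4, an inhibitor of mTORC1, by 2.41 ± 0.15, CTH, the transsulfuration enzyme cystathionine gamma-lyase, by 2.27 ± 0.16 (1.13 and 0.53 on its other probes, the latter not passing), the pseudokinase TRIB3 by 2.12 ± 0.16 and PPP1R27 by 1.80. CCL8 (-1.87 ± 0.16), MAT2A, which makes S-adenosylmethionine (-1.86 ± 0.15), RAB7B (-1.62), the translation factor EIF5 (-1.62, against 0.12 and -0.19 on 2 dim probes that did not pass) and the heat shock protein gene HSPA1B (-1.47) fell most.

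Of 14 heat shock genes 7 fell (9 over the list alone), with a median of -0.60, among them HSPA1A (-1.18), HSPH1 (-0.90) and HSPA8 (-0.87). Of 10 metallothionein and zinc genes 5 fell, MT1F (-1.02), MT2A (-0.73), the zinc exporter SLC30A1 (-0.69), and MT1G and MT1H near background, with a median of -0.44. The list members given here for the change in untreated cells were chosen after their values were seen. Of 15 NRF2 targets 1 fell (4 over the list alone), NQO1 (-0.84). Of 19 unfolded protein response genes 6 rose and 1 fell (7 and 1 over the list alone). Those that rose were TRIB3, ATF4 (1.26), DDIT3 (1.23), ASNS, which makes asparagine (0.92), XBP1 (0.68) and SESN2, near background at 8 h, most of them known targets or parts of the integrated stress response, while the ER protein SDF2L1 fell (-0.87). The median of the list was 0.04 and its mean 0.34. With an estimated correlation the adjusted p was 0.0047 for heat shock and 0.0375 for each of the other 3 lists, and with a common median 0.0425 for heat shock and metallothioneins, 0.186 for NRF2 targets and 0.221 for the unfolded protein response.

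Preset calls for cytokines (3 of 18 rose), remodelling (1 of 20 rose), lipid handling (3 of 23 rose) and MHC genes (0 of 18 passed) ended with an estimated correlation (adjusted p = 0.103, 0.103, 0.0506 and 0.0506). The remaining 18 lists were not called, among them chemokines (2 rose and 2 fell of 22) and NF-kB targets (2 rose and 3 fell of 24), and the reference genes had a median of 0.01. In all 921 genes passed, 443 higher and 478 lower. Calls numbered 365 and 315 without untreated 8 h replicates 1 and 2, and 366 and 349 without untreated 24 h replicates 1 and 2. Of the 443 higher genes 336 were also higher at 24 h in SAA1-treated cells, which share no array with them, and of the 478 lower genes 352 were lower (30.25 and 26.49 expected for independent lists).

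**Figure D3:**
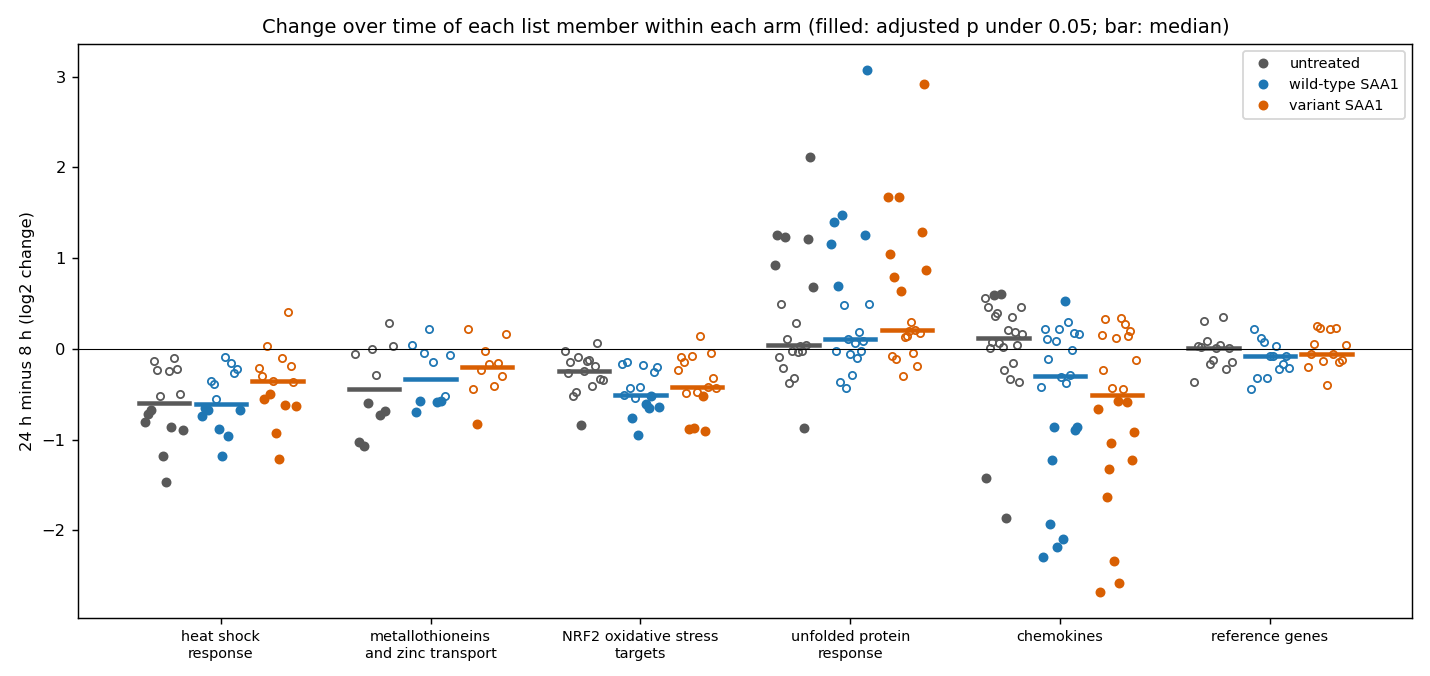
Log2 change from 8 h to 24 h (vertical axis) of each tested member of 6 lists in untreated, wild-type SAA1 and variant SAA1 cells, with filled points for adjusted p under 0.05 and bars for medians. In untreated cells the heat shock median was -0.60 and the reference gene median 0.01.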

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

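The test of whether a rise of the untreated baseline was the whole cause of the smaller response was chosen only after the result was seen, and so were the checks on arrays held out.

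The response to wild-type SAA1 differed between 8 h and 24 h for 14 named genes, by limma's test of the difference between the times. It shrank by 24 h for CCL4L1 (-2.79, from 4.25 to 1.46), TNFAIP6 (-2.89, from 3.94 to 1.05), CCL3 (-2.53, from 3.19 to 0.66) and MCOLN2 (-2.13, from 2.23 to 0.10), with adjusted p-values of 1.53e-08 to 1.44e-06. It shrank too for CD40 (-1.77), SLC2A6 (-1.69), TNFAIP2 (-1.62), OLR1 (-1.52), CXCL8 (-1.32) and the near-identical CCL3L1 and CCL3L3 (-1.58 and -1.26). The fitted changes of IL23A (-2.37) and LAMP3 (-1.79) are not measured sizes, since untreated cells were not above background for IL23A at 8 h and for LAMP3 at either time. Their levels in wild-type arrays, all above background, changed by -1.60 and -1.94. VCL went the other way (1.11, adjusted p = 0.0152), being lower at 8 h (-1.03) and not passing at 24 h (0.08). From 8 h to 24 h VCL fell in untreated arrays (-0.66, adjusted p = 0.0096), and its rise in wild-type arrays (0.45) did not pass. The difference between variant and wild-type SAA1 passed for ZNF749 (adjusted p = 0.0222). Its fitted change of -1.42 is not a measured size, since it was above background in wild-type arrays at 24 h alone, and its call ended with quantile normalization, with cyclic loess and with the mean over probes.

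For the 25 genes called lower in this test, of which 24 were raised at 8 h, the median response was 2.03 at 8 h and 0.40 at 24 h, and with the variant 1.98 and 0.48. Array scaling was argued against, since 96.0% of them (24 of 25) kept call and sign with quantile normalization. A weak or mislabelled treatment of the wild-type arrays at 24 h was argued against by the variant arrays, whose levels of the same genes changed by a median of -0.99. A rise of the untreated baseline was not the whole cause, since levels in the wild-type arrays themselves changed by a median of -1.22, but it was part of it. The response is the difference from untreated arrays, so a rise in those lowers it by construction. The median rise of 0.46, or 30.1% of the median fall, may be inflated, since the genes were picked by a test that contains it. With 1 untreated array of each time held out while 12 to 14 genes were picked, the rise on the arrays held out had medians of 0.37 to 0.55 over the 4 choices. Wild-type arrays held out in the same way changed by medians of -1.45 to -0.64. Among the named genes the rise in untreated arrays passed on its own for IL23A (adjusted p = 0.0044), CCL3 (adjusted p = 0.0368), CCL4L1 (adjusted p = 0.0292) and OLR1 (adjusted p = 0.0190). IL23A was not above background there at 8 h, and SLC2A6 fell in untreated arrays (adjusted p = 0.0203). What raised the baseline stayed open. A transient induction that faded by 24 h is consistent with these values, as a hypothesis found and tested on the same arrays, and consumption of the protein was not tested.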

How the results depend on the processing

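With 2 arrays per group, 1 array can decide a call, and 28.00% to 30.22% of probes lay above background. Scaling to a common median, cyclic loess, the estimated-background filters and the genes raised for the mean of both proteins were chosen only after the data had been seen. Background correction with detection p-values, detection filters and a chip block were not run, and the authors' processed values are the values used throughout. The cause of the changes below was not tested, except that stricter thresholds call fewer genes by construction. A common median moves all genes of an array by the same amount. It lines arrays up on probes at background, since every array's median signal lay below its estimated background limit. Counts below are of genes passing, the proteins' own contrasts being wild-type or variant against untreated. Genes raised for the mean of both proteins were picked anew in each setting. Leaving out 1 array of a protein tilts that picking towards genes high on its other array.

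With normexp and quantile, wild-type SAA1 gave 282 genes at 8 h and 57 at 24 h, the variant 201 at 8 h, time in untreated cells 1386, the change of the wild-type response 42 and the change of the difference between proteins 0. Between variant and wild type at 24 h the test of NF-kB targets (median -0.106) and of hypoxia genes (-0.105) reversed, and the difference over genes raised for that mean was -0.049 at 8 h, no longer passing, and -0.127 at 24 h, now passing. Quantile alone gave 0 for the change of the difference, -0.117 and -0.112 for the reversed lists and -0.137 at 24 h, now passing. Cyclic loess gave 0, -0.135, -0.123, -0.068 at 8 h, no longer passing, and -0.143 at 24 h, now passing. A common median moved the comparisons by 0.110, -0.056, -0.065, 0.173, 0.045, 0.116, 0.005, -0.166 and 0.238 and gave 282 genes between the proteins at 24 h, 112 for the variant at 24 h, 44 for the change of the response, 11 for the change of the difference, and -0.161 at 8 h, no longer passing.

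The mean over probes gave 0 for the change of the difference, and so did fitting the compared groups only. Every probe on its own gave 2 between the proteins and 42 for the variant at 24 h. Trend and robust settings gave 66 for wild-type SAA1 at 24 h, 13 between the proteins at 24 h, 187 and 53 for the variant and 47 for the change of the response. Requiring 2-fold gave 59, 17, 44, 15 and 101 for wild-type SAA1, the variant and time, and treat at 1.2-fold 63, 16, 45, 10 and 171, with 15 and 0 for the changes between times. Separated arrays with 2-fold and no p, where chance separates 33.3% of genes, gave 59, 17, 1 between the proteins at 24 h, 45, 15 and 102. With replicate numbers as a block the counts were 183, 42, 0, 0, 142, 30, 967, 30 and 1. By their correlations (-0.088 to 0.185) replicate numbers do not pair the samples throughout. Only 3 of 15 pairs of groups exceeded 0.1, all of them between SAA1-treated groups. The next counts cover the design comparisons alone, wild-type SAA1 against untreated and variant against wild-type SAA1 at each time. They leave out the stricter thresholds, the separated arrays and every probe on its own, and list results used the preset correlation. Within them 1 gene or list can count several times, once per comparison and setting. Of results for single named genes, 154 no longer passed, 10 newly passed and 2606 stayed the same. Of results for lists, 112 no longer passed, 35 newly passed, 6 reversed and 2423 stayed the same.

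Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 84 to 193 and 18 to 79 genes for wild-type SAA1 at 8 h and 24 h, 0 to 0 and 0 to 8 between the proteins, 56 to 140 and 10 to 33 for the variant, 315 to 989 for time, 17 to 42 and 0 to 1 for the changes between times, and differences over genes raised for that mean of -0.207 to -0.044 at 8 h and -0.206 to -0.044 at 24 h.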

Other observations

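Both SAA1 proteins gave an early chemokine and NF-kB response, a kind also known in macrophages for Toll-like receptor ligands, which no array here received. At 8 h 71 of the higher genes were shared between the proteins. For all 164 genes called higher for the mean of both proteins, the difference between them had a confidence interval within 2-fold. That limit is wider than their median response of 0.72 log2, so it does not show that the proteins act alike. Over those 164 genes the variant lay slightly lower (-0.107). Other settings picked the genes anew, so effect and choice of genes are mixed in their values. The difference no longer passed with normexp and quantile (-0.049), cyclic loess (-0.068) or a common median (-0.161). It stayed negative with each array left out (-0.207 to -0.044). Its lowest value came without wild-type replicate 2 at 8 h and its highest without variant replicate 2 at 8 h. Leaving out 1 array of a protein makes the picking favour genes high on its other array. That range therefore cannot show how firm the difference is. Over the 32 genes raised at 24 h the difference of -0.074 did not pass. With genes picked anew it passed with normexp and quantile (-0.127), quantile (-0.137) and cyclic loess (-0.143). A common median, which moves all genes of an array alike, gave 0.099. For the 81 genes lowered at 8 h the response to the variant was not weaker (median difference -0.039). Whether the proteins differ in strength stayed open, since the difference changed with the scaling. At 24 h it ran from -0.206 to -0.044 with each array left out in turn, with the same limit from the picking. Bacterial ligands carried with the protein could give a like response, and were not tested, since no array had such a control.

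The test of how much quantile normalization removes was chosen only after the result was seen, and so were the lists of amino acid genes and tRNA synthetases and the split of the unfolded protein list.

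Between variant and wild-type SAA1 at 24 h, 0 genes passed in limma but 3058 had an unadjusted p under 0.05, 987 higher and 2071 lower with the variant, where chance gives 1212. An array background left by scaling to a common mean would push dim genes 1 way and bright genes the other. Across genes, which are not independent replicates, the difference followed mean level with Spearman's rho of 0.525. Quantile normalization removed 82.6% of the excess (from 1846 to 322 genes). Both would follow from that explanation. Quantile normalization gives all arrays the same distribution, so it would remove a difference that follows level whatever its cause. The low-signal mode lay at signals of 41.06 and 42.99 on wild-type arrays at 24 h. On variant arrays at 24 h it lay at 37.46 and 36.42. That the variant changes the response of SAA1-responsive genes stayed open: 2 of the 44 genes called for the mean of both proteins at 24 h (4.5%, exact 95% interval 0.6% to 15.5%) had an unadjusted p under 0.05, against 12.6% of all genes. The interval reaches above 12.6%, so the bound set beforehand was too lenient to exclude it. The 12.6% also contains the excess described above, so it is not a rate expected without a difference. For that reason too the test cannot decide.

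In untreated cells at 24 h, genes of amino acid synthesis and transport were higher than at 8 h: 15 of 20 rose, with a median of 0.84, among them CTH (2.27), SLC7A5 (1.63) and PSAT1 (1.37), genes chosen after their values were seen. The 12 tRNA synthetases known as targets of the transcription factor ATF4 had a median of 0.71 and 8 of them rose, with AARS1 the highest (1.71). The other 22 synthetases had a median of -0.09 and 0 rose. The difference of 0.80 (two-sided permutation p = 1e-05 over 100000 resamples, the smallest these can give, with genes not independent) is consistent with an ATF4-driven amino acid response, as a hypothesis found on these arrays. Folding stress in the ER was argued against, since 11 ER chaperones changed by a median of -0.04, although XBP1, a folding-stress gene left out of both parts of the split list, rose by 0.68 (median -0.03 with it included). Also argued against was a fault of the untreated arrays alone, since the treated arrays gave 0.80 for the same synthetases. The labels name a batch, chip or day for 0 samples, so array batch or handling day tied to time and the time in culture cannot be told apart.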
